A study of Homo sapiens with 6 samples.

How the data were processed

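RNA of 6 cell samples labelled NCI-H929 was hybridised to 1 Affymetrix array each, 3 for PRMT5_down and 3 for control. The series text and titles speak of sponges and the treatment protocol of a short hairpin RNA vector. The deposited values are log2 signals per probe set, made by the authors with RMA per the submitters' processing notes, and the software version and chip definition are not given in the sources used here. RMA fits all arrays together and evens out their distributions, so a change shared by most genes would not show. The file holds 2 decimals. Values were used as deposited.

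Of 49372 probe sets, 79 were controls, 44994 had 1 gene symbol, 1832 had several and 2473 were unnamed here. Symbols were updated through gene identifiers for 44967 probe sets. Each of 18132 genes was represented by its brightest single-symbol probe set, with no filter on dim ones. Those with several symbols or none were tested apart, with 0 of 4305 called by limma, 39 of them at an unadjusted p under 0.05. The background was the 95th percentile of 333 olfactory receptor genes on each array. Genome positions were not used here.

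PRMT5_down was compared with control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Before the data were examined, 32 gene lists were written, and limma camera with a preset correlation of 0.01 tested each, adjusted over the lists. Lists of erythroid and plasma cell genes were added later, before they were tested. The named genes were fixed beforehand: PRMT5 and its complex, the 5 genes with the smallest p in each direction as none was called, CASP1 and the 3 pyroptosis genes with the smallest p, and up to 4 genes of each other list described with the smallest p. Levels of lineage genes and the genes of the closing section outside this rule were chosen after their values were seen.

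Both groups carry replicate numbers 1 to 3. Deviations from the group means correlated across genes at r = 0.82, 0.72 and 0.79 between arrays of the same number, over the 0.1 set as minimum, so the numbers were taken to pair the arrays. That pairing comes from the data, since the labels do not say what a number shares. The planned fit has no block. The fit with the replicate block left 0 genes called and 1496 at an unadjusted p under 0.05.

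On simulated data made for PRMT5_down against control with 18132 genes, the planned fit recovered 0% of genes changed by 0.5 log2 units, 52% at 1, 82% at 2 and 100% at 3, with 0 false calls. With the replicate block 96% were recovered at 0.5, and 19 of 217 calls were false. The simulated noise followed the block fit and was independent between genes, so recovery on the arrays may be lower. There PRMT5, at -0.98, missed with the block (limma adjusted p = 0.21). The simulated shares therefore do not exclude changes of such sizes. Alternatives tried were other normalization, filters, probe set rules, variance models, array weights, left-out arrays and other list tests.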

Results

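Gene expression was measured on 6 Affymetrix arrays hybridised with RNA from cells labelled NCI-H929, a human multiple myeloma line. In 3 arrays the cells carried a lentivirus meant to lower PRMT5, the main enzyme of symmetric arginine dimethylation, and in the other 3 a control lentivirus. Per the labels' protocols, transduced cells were selected with puromycin and collected at the same time. The values are log2 signals, and the array medians lay between 5.29 and 5.32. Only 3 arrays per group limit the precision of every difference. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The stated question was which genes may be PRMT5 targets.

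PRMT5, the targeted gene, was lower in the arrays of the PRMT5-lowering lentivirus. Its signal was 9.93, 10.35 and 10.30 in control replicates 1, 2 and 3 and 8.63, 9.65 and 9.37 in PRMT5_down replicates 1, 2 and 3. The means were 10.19 ± 0.23 in controls and 9.22 ± 0.53 in PRMT5_down (SD, n = 3 each), a log2 difference of -0.98 (SE 0.28). Within each replicate number, PRMT5 stood at 40.6%, 61.6% and 52.5% of its control. All 3 values lay below all 3 controls, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. The two-sided exact permutation within the 3 pairs gave p = 0.25, also the smallest possible. Over all genes the difference did not pass limma (adjusted p = 1). It also missed with the replicate number as a replicate block (limma adjusted p = 0.21). Taken alone, as the gene targeted, PRMT5 had an unadjusted limma p of 0.013 as planned and 3.8e-05 with the block. Of the partners of PRMT5, WDR77 differed by 0.16 (SE 0.22), CLNS1A by -0.18 (SE 0.16), RIOK1 by 0.21 (SE 0.18) and COPRS by 0.08 (SE 0.20), and none passed. The 5 genes of the PRMT5 complex had a mean log2 difference of -0.14 and a median of 0.08, opposite in sign, with a limma camera adjusted p of 0.75.

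**Figure D1:**
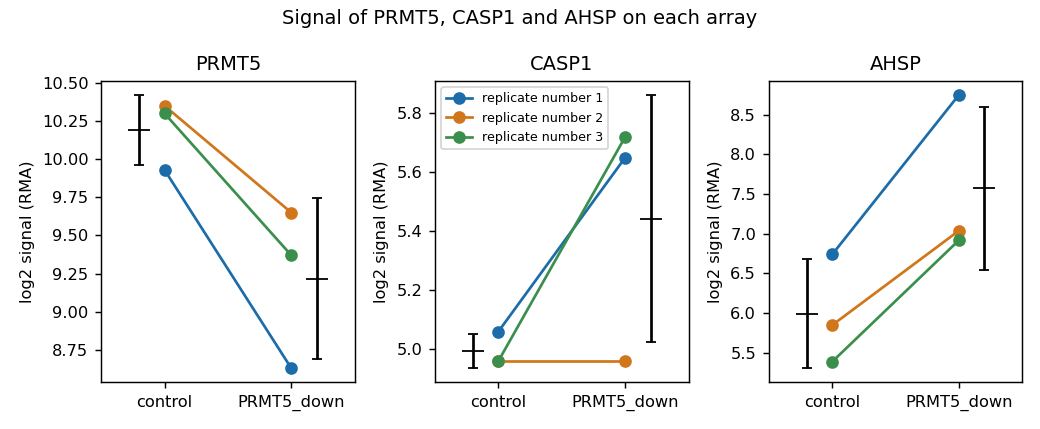
Log2 signal of PRMT5, CASP1 and AHSP in control and PRMT5_down arrays. Coloured points joined by a line share a replicate number, and black marks with bars give the mean and SD of 3 arrays. PRMT5 is lower and AHSP higher in each of the 3 numbers, while CASP1 differs by 0.00 in replicate number 2.

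No gene passed the test between PRMT5_down and control. Among 18132 genes, limma called 0 at an adjusted p under 0.05, and 149 had an unadjusted p under 0.05, 60 higher and 89 lower, where chance gives about 906.6. The genes with the smallest p that were higher in PRMT5_down, none of which passed, were RCBTB2 with a log2 difference of 0.58 (SE 0.12), SAMD9 with 1.10 (SE 0.26) from control signals under background, PPARA with 0.59 (SE 0.14), CLCN4 with 0.49 (SE 0.13) and CD52 with 0.35 (SE 0.09). PPARA encodes a nuclear receptor of fatty acid metabolism and CD52 a lymphocyte surface glycoprotein. On the lower side, also without passing, stood the amino acid transporter gene SLC7A8 at -0.52 (SE 0.10), the mitochondrial ribosomal protein gene MRPL24 at -0.73 (SE 0.16), TMEM86B, not above background on any array, at -0.44 (SE 0.11), the RNA polymerase I subunit gene POLR1E at -0.33 (SE 0.08) and the mitochondrial tryptophan tRNA ligase gene WARS2 at -0.38 (SE 0.10). With the mean of a gene's probe sets in place of the brightest, the differences were 0.35 for RCBTB2, 0.13 for PPARA, 0.28 for CLCN4 and -0.17 for WARS2. The groups did not overlap for 711 genes, or 3.92%, where chance gives 10% for arrays that are not paired. The difference went one way in all 3 replicate numbers for 4873 genes, or 26.9%, where chance gives 25%. A mean difference of at least 2-fold was seen for 7 genes, all higher in PRMT5_down. With the replicate block, limma still called 0 genes, and 1496 had an unadjusted p under 0.05, above the 906.6 of chance. Another split of the arrays gave 1206 with the block. The planned fit leaves the spread between replicate numbers in its standard errors. For PRMT5 the SE was 0.28 as planned and 0.12 with the block. The 149 genes of the planned fit therefore do not show that differences are absent.

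CASP1, the inflammatory caspase of pyroptosis, had a log2 difference of 0.45 (SE 0.21) and did not pass (limma adjusted p = 1). Its mean signal was 4.99 ± 0.06 in controls and 5.44 ± 0.42 in PRMT5_down (SD, n = 3 each), close to the background of 4.89 to 5.01 set by olfactory receptor genes. Within replicate numbers 1, 2 and 3, CASP1 differed by 0.59, 0.00 and 0.76. A probe set shared with its neighbour CARD16, above background on all 6 arrays, differed by 0.85, 0.01 and 0.73. Another CASP1 probe set, above background on no array, differed by 0.77, 0.44 and 1.02. Over all its probe sets, CASP1 had mean differences from -0.05 to 0.95. Its value was 0.89 with its most variable probe set, 0.24 with array weights and 0.31 to 0.69 with 1 array left out. Its neighbour and near-copy CARD16 differed by 0.48 (SE 0.28) and the gasdermin gene GSDMA, not above background on any array, by -0.12 (SE 0.08). CARD16, above background on all 6 arrays, differed by 0.51, 0.15 and 0.77 in replicate numbers 1, 2 and 3. With the replicate block, the unadjusted limma p was 0.013 for CASP1, 0.0042 for CARD16 and 0.19 for GSDMA. None of them passed there (limma adjusted p = 0.56, 0.52 and 0.69). Of 27 measured genes of pyroptosis and the inflammasome, 10 were higher and 17 lower, with 0 called over all genes and 0 adjusted over the list alone. Only 12 of the 27 were above background on all 6 arrays, and 11 were at or below it on all 6. The counts therefore include genes with no clear signal. The list had a mean of 0.00 and a median of -0.05, and limma camera gave an adjusted p of 0.95.

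Replication-dependent histones and mitosis genes were called higher as lists, by small amounts, the only 2 of 32 called in the planned fit. Of 21 histone genes 15 were higher, with a mean log2 difference of 0.14 (limma camera adjusted p = 0.03), and of 34 mitosis genes 26 were higher, with a mean of 0.10 (limma camera adjusted p = 0.04). Both calls ended with an estimated correlation (limma camera adjusted p = 0.88 for histones and 0.89 for mitosis) and in fry, which tests against no change (limma fry adjusted p = 1.00 for both). In the planned fit no member passed over all genes, and 0 did when adjusted over the list alone. With the replicate block 1 mitosis gene and 0 histones passed over the list alone, and 0 of either list over all genes. Among the histones, H3C10 differed by 0.33 (SE 0.21), H3C2 by 0.47 (SE 0.33), H2AC13 by 0.37 (SE 0.26) and H1-2 by 0.20 (SE 0.14). Among the mitosis genes, the kinetochore gene CENPF differed by 0.46 (SE 0.21), the proliferation marker MKI67 by 0.31 (SE 0.17), AURKB by -0.13 (SE 0.10) and ECT2 by 0.33 (SE 0.27). The histone mean was 0.35, 0.01 and 0.06 in replicate numbers 1, 2 and 3, and the mitosis mean 0.02, 0.07 and 0.22. Without control replicate 3 the mitosis list turned lower (limma camera adjusted p = 0.16), and the histones missed (limma camera adjusted p = 0.17). Without PRMT5_down replicate 1 or 2 neither list passed (limma camera adjusted p = 0.23 and 0.26 for histones and 0.20 and 0.92 for mitosis), nor did the histones without control replicate 1 (limma camera adjusted p = 0.33). Both lists stayed called with ranks, without PRMT5_down replicate 3 and without control replicate 2. They were also called with the replicate block (limma camera adjusted p = 0.0014 for histones and 0.00042 for mitosis). With the block and an estimated correlation both missed (limma camera adjusted p = 0.62 for each).

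Interferon-stimulated genes did not pass (limma camera adjusted p = 0.15). Of 35 measured, 21 were higher and 14 lower, with a mean of 0.12 and a median of 0.02. Only 14 of the 35 were above background on all 6 arrays, and 19 were at or below it on all 6. SAMD9 differed by 1.10 (SE 0.26), SP110 differed by 0.68 (SE 0.31), PARP9 by 0.52 (SE 0.24) and IFIT3, not above background on any array, by -0.22 (SE 0.10). With the replicate block, limma gave 11 members an unadjusted p under 0.05. Adjusted over the list alone 4 members passed there, and 0 did over all genes. The list was called with the block (limma camera adjusted p = 0.03), and it missed with the block and an estimated correlation (limma camera adjusted p = 0.62). It was also called without control replicate 2 (limma camera adjusted p = 0.02) and with the dimmest 30% or 50% of genes left out (0.00039 and 0.0035). Without any other single array it missed (limma camera adjusted p from 0.09 to 0.82, the highest without control replicate 1). With the block, it was called without pair 2 (limma camera adjusted p = 0.04). It missed there without pair 1 or 3 (0.29 and 0.07).

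**Figure D2:**
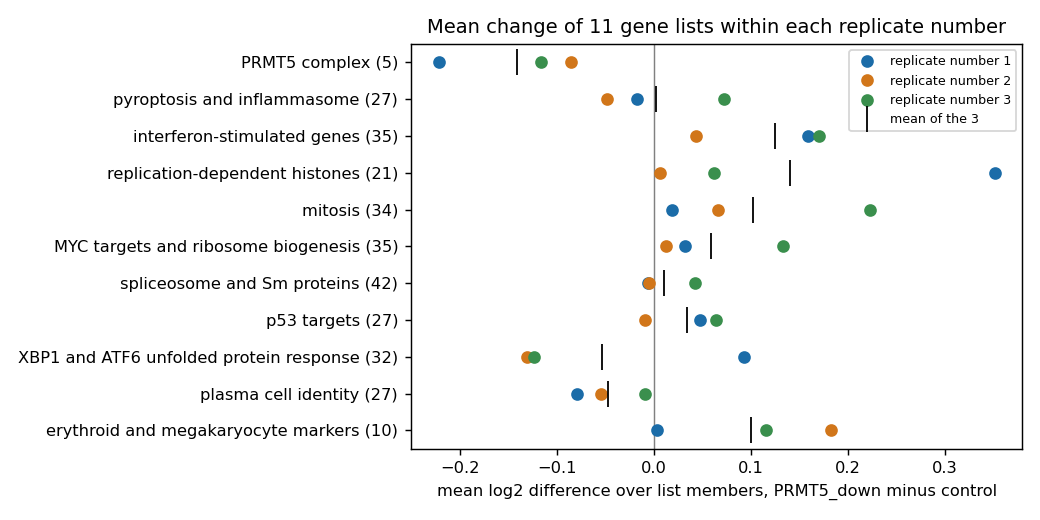
Mean log2 difference, PRMT5_down minus control, over the members of 11 gene lists. Coloured points give each replicate number, the black line their mean, and the count of measured genes stands in brackets. The histone mean is 0.35 in replicate number 1 and 0.01 in number 2.

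Ribosome biogenesis genes, splicing genes, p53 targets and the unfolded protein response did not pass. MYC targets and ribosome biogenesis had 22 of 35 genes higher, with a mean of 0.06 (limma camera adjusted p = 0.11), NIP7 at 0.27 (SE 0.14), UTP15 at 0.33 (SE 0.20), NOP2 at 0.41 (SE 0.26) and NOP16 at 0.14 (SE 0.10). Spliceosome and Sm proteins, some of them known PRMT5 substrates, had 25 of 42 higher, with a mean of 0.01 (limma camera adjusted p = 0.39). SNRPA differed by -0.27 (SE 0.13), SNRPC by -0.20 (SE 0.12), SNRNP200 by 0.15 (SE 0.10) and PRPF8 by 0.16 (SE 0.13). The p53 targets had 18 of 27 higher, with a mean of 0.03 (limma camera adjusted p = 0.32), FAS at 0.13 (SE 0.11), MDM2 at 0.36 (SE 0.35), TP53INP1 at 0.28 (SE 0.32) and SESN2 at -0.21 (SE 0.25). MDM2 was at 0.01 without control replicate 3, and FAS was not above background on any array. Of 32 genes of the XBP1 and ATF6 response 24 were lower, with a mean of -0.05 overall and of 0.09, -0.13 and -0.12 in replicate numbers 1, 2 and 3 (limma camera adjusted p = 0.37), among them CRELD2 at -0.29 (SE 0.19), MANF at -0.27 (SE 0.20), HERPUD1 at -0.16 (SE 0.14) and SEC24D at -0.12 (SE 0.11). Single arrays decided some of these: without control replicate 2 limma camera called ribosome biogenesis (adjusted p = 0.0033) and splicing genes (adjusted p = 0.030), and without PRMT5_down replicate 1 ribosome biogenesis (adjusted p = 0.020) and, lower, the XBP1 and ATF6 response (adjusted p = 0.038). With the replicate block and pair 1 left out, limma camera also called that response lower (adjusted p = 7.9e-05).

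Some genes of the plasma cell identity list were under background on all 6 arrays, while others were high. How specific each gene is to plasma cells was not tested. IRF4, the plasma cell transcription factor, had a mean signal of 3.20, the surface marker CD38 2.61, TNFRSF17 2.47, MZB1 2.92 and POU2AF1 2.59, all under the background on each array. Other genes of the plasma cell identity list lay well above it, such as XBP1 at 10.43, CCND2 at 10.36, NSD2 at 9.05 and FGFR3 at 8.63. In all, 14 of its 27 genes were above background on all 6 arrays, and 12 were at or below it on all 6. The erythroid heme enzyme ALAS2 had a mean of 10.18 and the transferrin receptor TFRC 11.47. Probe sets shared by the gamma globin genes HBG1 and HBG2 had means of 12.12 to 13.41. Levels of different probe sets are not on one scale, so these are set against background only.

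Between the groups, 22 of the 27 plasma cell genes were lower, with a mean of -0.05 (limma camera adjusted p = 0.16), and the list did not pass. SDC1 differed by -0.24 (SE 0.12), IGKC by -0.20 (SE 0.10), FGFR3 by 0.19 (SE 0.11) and FKBP11 by -0.23 (SE 0.14). Of 10 erythroid and megakaryocyte markers 6 were higher, with a mean of 0.10 (limma camera adjusted p = 0.16). ALAS2 differed by 0.24 (SE 0.11), TFRC by 0.53 (SE 0.31), the erythropoietin receptor EPOR by 0.25 (SE 0.16) and PF4 by -0.18 (SE 0.13). PF4 and IGKC were not above background on any array. The erythroid list was called higher without PRMT5_down replicate 1 (limma camera adjusted p = 0.045).

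**Figure D3:**
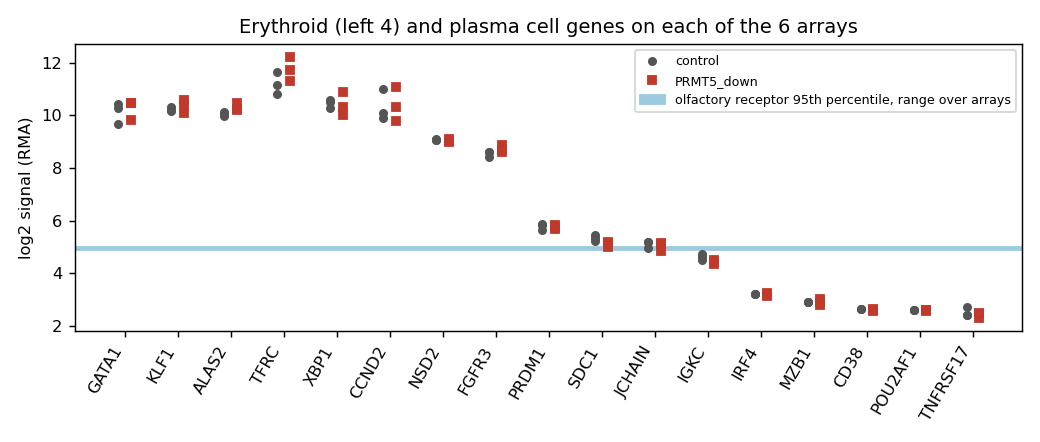
Log2 signal of erythroid and plasma cell genes on each array, with controls as grey circles and PRMT5_down as red squares. The blue band is the background, 4.89 to 5.01. IRF4, MZB1, CD38, POU2AF1 and TNFRSF17 lie under it on all 6 arrays.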

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

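Settings that combine the replicate block with another choice, or leave out a pair of arrays, were chosen after seeing the data. PRMT5 was lower under every setting run, from -0.68 to -1.19 with 1 array left out in turn. Its limma call, absent otherwise, appeared with the replicate block, trend and robust (log2 difference -0.98, adjusted p = 0.03) and with the replicate block, lowest 50% left out (-0.98, adjusted p = 0.04). Under each of those settings limma called 3 genes, AHSP, PRG2 and PRMT5, against 0 in the planned fit and under all other settings; the cause was not tested. Genes at an unadjusted p under 0.05 numbered 149 as planned, 1496 with the replicate block, 57 and 23 with the lowest 30% and 50% left out (fewer genes tested), 230 with trend and robust, 466 over all probe sets, 9 with treat at 1.2-fold, and 92 to 285 with 1 array left out. With the block they numbered 429, 1734 and 620 without pair 1, 2 or 3, 1544 with trend and robust and 885 with the lowest 50% left out. The median difference of all genes was -0.017 as planned and -0.015 after quantile normalization.

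The 2 called lists became 0 with quantile normalization again, the mean of probe sets, the most variable probe set, array weights, estimated correlation, fry, and the replicate block with estimated correlation. They were 3 with the replicate block, and 4 and 5 with the replicate block and pair 1 or pair 2 left out. Leaving out 1 array gave 0 to 10, with 10 without control replicate 2, 4 without PRMT5_down replicate 1 and 5 without PRMT5_down replicate 3. Camera took the variance trend only, as it has no robust option. Direction turned for the following, not called where it turned. COPRS was at -0.048 and -0.055 without PRMT5_down replicate 3 and control replicate 1, within -0.055 to 0.27 over the left-out arrays, TP53INP1 at -0.053 without PRMT5_down replicate 1, within -0.053 to 0.49, and MKI67 at -0.027 with the most variable probe set. In camera adjusted p, the PRMT5 complex turned at 0.83 (ranks) and 0.86 (replicate block, pair 3 left out). Pyroptosis turned at 0.94 (quantile normalization again), 0.98 (lowest 50% left out), 0.92 and 0.62 (replicate block, pair 1 or 2 left out) and 0.97 (replicate block, lowest 50% left out), and without PRMT5_down replicate 1 or 2 or control replicate 2, over a range of 0.54 to 0.99 with 1 array left out. Spliceosome genes turned without PRMT5_down replicate 2 or control replicate 3, over a range of 0.030 (called higher, without control replicate 2) to 1.00. The XBP1 and ATF6 response turned without PRMT5_down replicate 2, over a range of 0.038 (called lower, without PRMT5_down replicate 1) to 1.00, and at 0.65 (replicate block, pair 2 left out). The plasma cell list turned at 0.90 and 0.97 with the lowest 50% left out, without and with the replicate block. The second plasma cell list turned at 0.67 (mean of probe sets), 0.70 (most variable probe set), 0.92 (array weights) and 0.55 (fry), and without PRMT5_down replicate 1 or control replicate 2, over a range of 0.68 to 0.98. The mitosis list, called as planned, turned at adjusted p 0.16 without control replicate 3, over a range of 1.8e-06 (without PRMT5_down replicate 3) to 0.92. The replicate block changed no call besides that of the interferon-stimulated genes. Of 56 named genes other than PRMT5, 48 moved by over 1.5 times under some planned setting, 20 by the choice of probe set and 40 by a left-out array. For 10, CASP1 included, signal was not above background on all 6 arrays.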

Other observations

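Chosen only after the result was seen were the tests of ribosomal protein genes, of the control transcripts and differences between numbers, of random lists, of RNA integrity and of other splits. The share of the added lists above background, and the camera test of the erythroid one with the replicate block, were set before. In 3 tests the rule written down was met, and a condition added after the values were seen left the answer open: the share of all genes above background for mixed cells, actin for shared handling as the whole cause and GAPDH for RNA integrity. The 7 genes at least 2-fold higher, named after their values were seen, were AHSP, PRG2, TAC3, GIMAP2, SAMD9, HEPACAM2 and SLC4A1, and none passed the planned test. AHSP, the chaperone of alpha globin, had a log2 difference of 1.58 (SE 0.58), with 2.01, 1.19 and 1.53 in replicate numbers 1, 2 and 3. The eosinophil granule protein gene PRG2 differed by 1.59 (SE 0.71) and the red cell anion exchanger gene SLC4A1 by 1.00 (SE 0.36). With 1 array left out, the lowest differences were under 2-fold: 0.99 for AHSP, 0.92 for PRG2, 0.69 for TAC3, 0.87 for SAMD9 and 0.73 for SLC4A1. With the replicate block, limma gave AHSP an adjusted p of 0.09 and PRG2 0.19. Of the second plasma cell list, 7 of 15 genes were higher (limma camera adjusted p = 0.91).

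Erythroid genes were high and several plasma cell genes near background on every array. A probe table out of step with the values was argued against, since 100% of cytosolic ribosomal protein genes lay among the brightest 10% of genes. Other cells mixed as a minority into a plasma cell culture stay open. Of the second plasma cell list, 8 of 15 genes were above background on all 6 arrays. The same held for 56.3% of all genes, so that the share decides nothing. RNA from a line of erythroid type in place of the labelled one may also be the source: 23 of 29 genes of the second erythroid list were above background, but the difference from the plasma cell list missed the threshold set before (two-sided Fisher's exact p = 0.092). The low signals of IRF4 and CD38 prompted the question, while XBP1, CCND2, NSD2 and FGFR3 of the plasma cell identity list were high. These levels were picked after they were seen, and how specific each gene is was not tested, so neither side decides. A test on 9 plasma cell genes, picked with those low signals known, was run and then dropped as circular.

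Arrays with one replicate number resembled each other more than arrays of one group: the number took 81.3% of the variance and the group 8.36%. Shared labelling or RNA handling may contribute, since the poly-A control mean ranged 5.54 times more between numbers than within them. Whether it is the whole cause stays open. Between numbers, 5.12% of genes differed by over 1 log2 unit and no poly-A control by over 0.58, but spiked controls do not show the state of the sample RNA. The 3-prime minus 5-prime actin signal also followed the number, at 1.22 and 1.09, 1.02 and 1.02, and 0.84 and 0.73 in PRMT5_down and control of numbers 1, 2 and 3.

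Erythroid genes of an added list were higher in the arrays with lower PRMT5, while the erythroid and megakaryocyte list fixed before the data were examined missed (limma camera adjusted p = 0.16, and 0.11 with the replicate block). The added list holds neither AHSP nor SLC4A1, but its class was chosen because such genes were seen higher on these arrays. It had 24 of 29 genes higher, a mean of 0.17, 0.16 and 0.19 in replicate numbers 1, 2 and 3, and with the replicate block a limma camera p of 2.4e-08 (adjusted over the 2 added lists, 4.8e-08, 0.048 with an estimated correlation and 0.00048 in fry); without the block the adjusted p was 2.1e-05, 0.18 with an estimated correlation, 0.55 in fry and 0.31 without PRMT5_down replicate 1. The rule set before, a p under 0.05 with the block and a mean above 0 in all 3 numbers, was met, on the same arrays that raised the question. The size of that blocked p overstates the evidence, since an estimated correlation brought the limma camera adjusted p to 0.048. Without the block the real split had a camera p of 1.1e-05. There 2 of the 9 other splits gave this list a smaller camera p, and 5 of the 9 a p under 0.05. With the block, the 3 other splits that part all pairs gave camera p of 0.0090, 0.043 and 0.078. Their list means were 0.045, 0.066 and -0.059, against 0.17 in the real split. They reuse the same 3 pair differences with signs turned, so they cannot weigh the blocked p. A shift of genes of like level was argued against by a mean at percentile 100 of 10000 matched random lists, while RNA integrity stays open: the mean lay 5.51 standard errors, taken across genes that vary together, above 0 in replicate number 2, a single pair. The 3-prime minus 5-prime signal differed by 0.13, 0.00 and 0.11 for actin and by -0.02, -0.04 and 0.01 for GAPDH in numbers 1, 2 and 3. GAPDH ranks the 3 numbers in the order of the list means, and actin ranks them in the order of the histone means (0.35, 0.01 and 0.06), for which RNA integrity was not tested. In either case 3 numbers are too few to decide.

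The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 called genes and the highest other 0; with a real count of 0 all 10 splits give as many by construction, so this comparison says nothing. Genes at an unadjusted p under 0.05 numbered 149 against 2625, with 7 splits as high, and called lists 2 against 13, with 8 as high. The splits with most genes keep a pair of arrays together, which points to the replicate numbers. Among the splits that part all 3 pairs, the others gave 39, 102 and 43 genes without the block and 358, 1206 and 244 with it, against 1496, and 1, 2 and 4 called lists with it, against 3.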
